A study of Bos taurus with 10 samples.

How the data were processed

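The series holds 10 two-channel cDNA microarrays of bovine tissue collected at peak lactation. Liver, mammary gland, mesenteric adipose, omental adipose and subcutaneous adipose tissue were each hybridised on 2 arrays against a reference standard mixed from tissues, once with the tissue in Cy3 and once with the tissue in Cy5. Per the labels' protocols, 20 ug of RNA was turned into aminoallyl-labelled cDNA, hybridised for 2 days at 42 C, scanned with a ScanArray 4000 and read with GenePix 4.0, with 4 spots per element over both slides of a sample. The 2 arrays of a tissue therefore carry the same RNA and count as 1 sample. No spread between animals can be computed, and no p-value is given for a difference between tissues, apart from 1 further fit in which the 3 depots stand as samples of adipose tissue.

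The values used are those of the series' deposited value table. The deposited values were taken as log2 ratios of the dyes, because 94 of them sit at a ceiling of 16.61, the log2 of 100000, and the labels do not name the base. Background correction and normalisation are not given in the sources used here. The median of an array ran from -1.32 to 0.71 as deposited. With the tissue in Cy5 it was near 0 for liver (0.026), mammary gland (-0.036), mesenteric (-0.025) and omental adipose tissue (-0.011). On the other arrays it lay away from 0, so the arrays had not all been centred alike. Results without centring carry this unevenness. Between 15970 and 16245 of the 16416 spots of an array had a value after the ceiling values were taken as missing, and 2402 values were missing in the deposited table. Channel intensities were not analysed here, so signal over background is unknown, no filter on dim spots was possible, and the number of arrays limits the precision.

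The direction of the ratio is not stated in the labels. The 2 arrays of each tissue correlated at -0.78 to -0.67 across spots, and arrays of the same dye orientation at 0.23 to 0.79, so the ratio is tied to the dye. Arrays with the tissue in Cy3 had their sign turned, which takes the ratio as Cy5 over Cy3. For the omental array with the tissue in Cy5 the labels disagree, since the description of the second channel names Cy5 and its dye label Cy3. The dye label was used, its correlation with the other omental array was -0.70, and the array was left out in 1 alternative. This direction is likely, not certain. Its basis is the design text's account of ratios as relative expression, and a pair of gene lists fixed before the data were examined: plasma proteins made by hepatocytes are higher in liver and milk proteins in mammary gland under this direction only. The position of those 2 lists is for that reason no independent result. With the opposite direction every difference in the report changes sign, and other genes lead in each tissue, which was counted after seeing the data.

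Gene names needed a reconstruction. In the value table, neighbouring positions are duplicate spots: an odd position and the next one correlated at 0.83 to 0.92 on each array, an even position and the next one at 0.03 to 0.10. The annotation table instead places the 2 identifiers of a clone 8448 positions apart, and values there correlated at -0.03 to 0.03 over 5377 clones. With identifiers taken at face value, different clones of a gene had unrelated profiles over the 5 tissues (mean cosine 0.02 over 323 pairs). After shifts and simpler block orders gave similar values near 0, print layouts were searched: the table follows 48 blocks of 171 elements, and the annotation follows 16 blocks. The layouts were first found with all genes, and a search on 475 genes was then repeated with 475 other genes held out. The best of the pairings of 768 annotation layouts with table layouts reached a mean cosine of 0.69 on the search genes and 0.74 on the held-out genes (median 0.95, 262 pairs). The next different layout reached 0.33 on the held-out genes, and the best of 2 searches with shuffled symbols reached 0.16 on their own genes. Because the layout had been found on all genes before the split, the held-out value is not blind. Tissue identity played no part in the search. Names were used for 20 source plates, whose median cosine was 0.68 to 0.97 and whose lowest mean cosine was 0.44. The last plates had 6 pairs with a mean cosine of 0.23, and their 126 annotation entries with 1 symbol, 59 of them placed on an element, were left unnamed. Every gene name in the text rests on this reconstruction, which was chosen after seeing the data, and a single clone can still carry a wrong name.

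Of the annotation's identifiers, 10884 had 1 gene symbol, 186 had several and 5346 had none. Names were updated through Entrez identifiers in the RefSeq gene table of assembly ARS-UCD2.0, where 5467 of 5472 named elements matched. The build of the deposited files is not given in the sources used here, so no coordinates are printed. The 5472 named elements stood for 4366 genes, 922 of them with more than 1 element, and 2736 elements had no name in use.

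Each array was centred on its median, the 2 neighbouring spots of an element were averaged, elements of a gene were averaged, and the 2 arrays of a tissue were averaged last. Centring had been planned as an alternative to the values as deposited. It became the main setting once the medians were seen, and the values as deposited became the alternative. Treating ceiling values as missing and leaving out names of the last plates were also chosen after seeing the data. A gene passed the size rule when the mean difference was at least 2-fold, had the same sign in both dye orientations and had a value on all arrays involved. The same rule was applied to the dye contrast, in which the sign of the second orientation is turned so that the tissue difference cancels from the mean. Because the rule asks for the same sign in both orientations, a gene past it for the tissues could not be counted in the dye contrast. Dye contrast counts therefore miss technical spread in such genes and give no rate of false calls. The error printed after ± is the distance of each orientation's value from their mean. A gene led in a tissue when it was at least 2-fold above each of the other 4 tissues and highest there in both orientations. For adipose tissue as a whole, each depot had to be at least 2-fold above liver and mammary gland. The distance between tissues was the SD of differences across genes.

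Of 29 gene lists fixed before the data were examined, 24 had the 3 or more measured genes needed. The median difference of a list was placed among 10000 random lists of the same size matched in 5 bins of mean log ratio, drawn with replacement. A list was said to lie above or below random lists when it was outside their central 95%. Over 120 such placements about 6 would be expected outside if list genes behaved as independent draws, and 65 were. Genes of a list may vary together, some lists share genes, and the comparisons share samples. The 65 also include placements of the 2 lists used for the direction of the ratio. Setting 65 against 6 is therefore no test. These placements describe these arrays only. The lists for acute phase proteins and for exocrine pancreas and gut had 0 measured genes. Skeletal muscle (MYOZ1, TCAP) and B cell and plasma cell markers (IGHM, LTB) had 2 each, and the erythroid and platelet list had 2 with a value on all arrays (GYPC, ITGA2B). IGHM passed the size rule in subcutaneous against visceral adipose tissue, and the other 5 of these genes passed it in no comparison. CA2, of the erythroid and platelet list, had values for mesenteric against omental adipose tissue only and passed there.

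A rule fixed before the data were examined set the genes open to naming. They were the 12 largest differences in each direction per comparison among genes past the size rule, and up to 4 members of a list with the largest differences. The 5 genes with the largest margins per tissue were added. Only part of the 12 are named per comparison, and the choice among them followed no fixed rule. Those passed over include SERPINA3-3 (8.58), HAVCR1 (8.23) and UNC13D (7.94) in liver against mammary gland. PPP1R16A (-3.85) in mammary gland against adipose tissue and GIMAP1 (-3.87) in subcutaneous against visceral adipose tissue were also passed over. Further genes named are said to be chosen after their values were seen. A fixed set was to be named in any case, of which only APOA1 had a named element. The caseins, LALBA, ALB, FABP4, ADIPOQ, LEP, FASN and PCK1 were not analysed here.

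The size rule and the list placement were tested on simulated dye swaps built from 4307 genes, their real dye offsets and real residuals, with 50 genes changed at each of 4 sizes. In liver against mammary gland the rule called 26 of 50 genes changed 2-fold, 49 of 50 changed 3-fold and 26 of 4107 unchanged genes. In mesenteric against omental adipose tissue it called 21 of 50, 50 of 50 and 24 of 4107. Of 50 lists of 20 unchanged genes, 1 was called in liver against mammary gland, and all 50 were called after a shift of 0.5 log2 units. The first count is largely set by how the lists were drawn. The second is no measure for real lists in that comparison, where differences had an SD of 0.892 against 0.315 in the dye contrast. For the 20 measured myeloid markers, random lists there spanned -0.202 to 0.544, so a median of 0.5 would not be called.

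Alternatives covered the normalisation (as deposited, quantile, equal median absolute deviation), thresholds of 1.5-fold and 3-fold, the agreement of orientations, the treatment of several elements and missing values, each orientation alone, depots left out of the adipose mean, and limma with the 3 depots as samples (adjusted p of 0.05 and 2-fold). In that fit liver and mammary gland have 1 sample each, and all spread comes from depots that are not replicates of a condition. Added after seeing the data were elements with disagreeing spots left out, ceiling values kept, subcutaneous set against a single visceral depot, and gene lists without subcutaneous adipose in the adipose mean. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.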

Results

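Gene expression was measured in 5 tissues of lactating cattle on 10 cDNA microarrays: liver, mammary gland, and mesenteric, omental and subcutaneous adipose tissue. Each tissue was represented by 1 RNA sample on 2 arrays of opposite dye orientation against a common reference mixed from tissues. Values were log2 ratios of tissue over reference, centred on each array's median. There was no biological replication, so differences between tissues are given with the dye orientation error (±) and without a p-value. The direction of the ratios is likely rather than stated. Between 15970 and 16245 spots per array had a value, and 4307 named genes had one on all arrays. Gene names rest on a reconstructed print layout.

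The largest distance between tissues lay between liver and subcutaneous adipose tissue, with an SD of differences across genes of 0.99 log2 units (0.27 in the dye contrast). Liver and mammary gland stood 0.89 (0.32) apart, and mammary gland lay 0.66 (0.26) from omental and 0.83 (0.27) from subcutaneous adipose tissue. Mesenteric and omental adipose tissue were closest, at 0.32 against 0.22 in the dye contrast. Subcutaneous adipose tissue lay 0.71 (0.23) from mesenteric and 0.65 (0.22) from omental adipose tissue, which is of the size of the distance from mammary gland to the visceral depots. In the 4 alternatives tried liver and subcutaneous adipose tissue stayed farthest apart (0.91 to 1.03) and mesenteric and omental adipose tissue closest (0.34 to 0.40), while liver and mammary gland ran from 0.75 to 0.99 and held no fixed rank between them (place 2 to 7 of 10). Genes are not independent replicates, and these SDs describe the 5 samples.

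**Figure D1:**
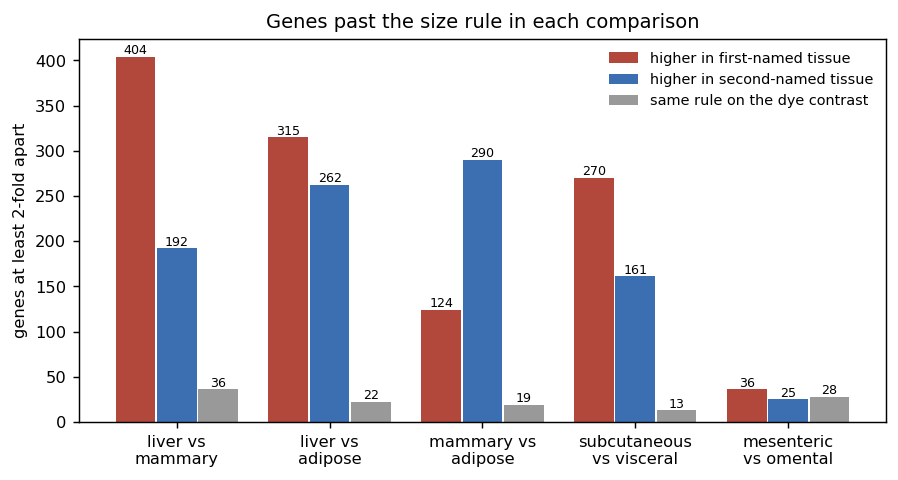
Number of genes at least 2-fold apart with the same sign in both dye orientations (vertical axis) for each comparison, split by the tissue in which they were higher, with the same rule on the dye contrast in grey. The dye contrast counts, of either sign, were 13 to 36 genes and by construction leave out genes past the rule for the tissues. In mesenteric against omental adipose tissue 28 genes stood in the dye contrast beside 61 past the rule (36 and 25).

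The first comparison set liver against mammary gland, organs that supply glucose and plasma proteins and that secrete milk. Most measured genes of fatty acid oxidation, cholesterol synthesis and plasma proteins were higher in liver, and most measured genes of milk secretion higher in mammary gland. RBP4, the plasma carrier of retinol, differed by 7.63 ± 0.35 log2 units (199-fold), TF (transferrin) by 5.66 ± 0.64 (50.5-fold), CAT (catalase) by 5.81 ± 0.39 and the bile acid transporter gene SLC10A1 by 5.56 ± 0.09. In the other direction, MFGE8, a protein of the milk fat globule membrane, differed by -6.68 ± 0.43 (103-fold higher in mammary gland), SPP1 (osteopontin) by -5.84 ± 0.12 (2 elements, -7.96 and -3.72) and PLIN2, a lipid droplet coat protein, by -4.23 ± 0.26.

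Of 13 genes of fatty acid oxidation and ketogenesis, 11 were higher in liver by the size rule and 2 did not pass (median 2.39). ACADS stood at 3.24 ± 0.10 and CPT1A, which controls the entry of fatty acids into mitochondria, at 3.20 ± 0.07. All 5 measured genes of cholesterol synthesis passed (median 2.31), led by ACAT2 at 3.92 ± 0.23 and EBP at 2.38 ± 0.00. Xenobiotic, bile acid and retinoid metabolism had 6 of 7 genes higher in liver (median 2.83), among them ABCC2 at 4.04 ± 0.02. Hepatocyte plasma proteins had 4 of 5 genes higher (median 3.33), with SERPING1 at 3.33 ± 0.14 and C4A at 3.05 ± 0.43, whereas APOA1 stood at 0.54 ± 0.52 and did not pass. In the urea cycle and amino acid list 2 of 4 genes passed, AHCY at 4.49 ± 0.02 and ASS1, an enzyme of the urea cycle, at 2.73 ± 0.15. Of 9 genes of gluconeogenesis and lactate, 4 were higher in liver, with the aminotransferase genes GOT2 at 2.24 ± 0.07 and GOT1 at 1.88 ± 0.01. The mitochondrial respiratory chain had 6 of 44 genes higher in liver and a median of 0.61, above random lists. The proteasome list had 2 of 26 genes higher, 1 lower (PSMD8, -1.05 ± 0.29) and a median of 0.35, also above random lists, but 0.10 and among them without the arrays that carried the tissue in Cy5.

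Of the 5 milk proteins and secretion genes, 4 were higher in mammary gland (median -2.60), with MUC1 at -3.09 ± 0.90, B4GALT1, the galactosyltransferase that forms lactose synthase, at -2.60 ± 0.41 and XDH at -1.86 ± 0.05. Lipogenesis had 4 of 8 genes higher in mammary gland (median -1.19), including ACSS1, which activates acetate, at -2.62 ± 0.61 and AGPAT1 at -2.10 ± 0.05. SREBF1 passed with a wide error, at -1.94 ± 1.83. Without the arrays that carried the tissue in Cy3, the lipogenesis median was -0.13 and no longer lay below random lists. Among 17 epithelial markers 8 were higher in mammary gland, including EHF at -3.88 ± 0.49, KRT19 at -3.21 ± 0.50 and ESRP1 at -2.82 ± 0.07. SPINT1 (4.38 ± 0.12) and KRT18 (1.09 ± 0.09), the latter chosen after its value was seen, were higher in liver. Extracellular matrix genes had a median of -0.71 with 6 of 24 higher in mammary gland, and 3 higher in liver: FN1 (fibronectin), which hepatocytes secrete, at 4.60 ± 0.05, and, named after their values were seen, FBLN2 at 1.71 ± 0.29 and COL12A1 at 1.27 ± 0.11. Of 11 smooth muscle and pericyte markers 3 were higher in mammary gland (median -0.47), led by TPM1 at -2.53 ± 0.35. Myeloid markers had 8 of 20 genes higher in liver (median 0.82), with the complement genes C1QB at 3.07 ± 0.21, C1QA at 2.90 ± 0.40 and C1QC at 2.48 ± 0.35, against SPP1.

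The proteasome and myeloid lists lay among random lists when the mean replaced the median, gluconeogenesis without the Cy3 arrays (0.55) and smooth muscle without the Cy5 arrays (-0.38). The remaining lists lay among random lists in this comparison. SLC30A4, a zinc transporter (-2.49 ± 0.39), and SLC2A1, the glucose transporter GLUT1 (-1.38 ± 0.09), were higher in mammary gland, and SLC27A2 (1.78 ± 0.03) and SLC29A1 (1.15 ± 0.29) in liver. IGFBP4 was higher in liver at 3.07 ± 0.07, as was the endothelial and lymphatic marker LYVE1 at 2.02 ± 0.14. In total 404 genes were higher in liver and 192 in mammary gland out of 4325 compared, against 36 in the dye contrast. Without centring, all genes shifted by a median of -0.22 and the split became 303 higher in liver and 301 in mammary gland. Of 119 genes past the rule with several elements, 112 had all elements in the same direction, and 70 had all of them past 2-fold. The print layout was chosen for agreement of clones and the genes by their mean, so this is no independent support for the names.

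The second comparison set liver against the mean of the 3 adipose depots. Most measured genes of xenobiotic metabolism and plasma proteins were again higher in liver, and most genes of the extracellular matrix higher in adipose tissue. SLC10A1 differed by 5.85 ± 0.14 log2 units (57.7-fold), TF by 5.12 ± 0.63, GAMT, which makes creatine, by 4.94 ± 0.06, DPP4 by 4.45 ± 0.23 and ABCC2 by 4.38 ± 0.36. LOC338050, listed in the gene table under the older name PCI, differed by 5.33 ± 0.10. COL1A2, a chain of type I collagen, differed by -4.36 ± 0.17 (20.6-fold higher in adipose tissue), FABP5, a fatty acid binding protein, by -3.97 ± 0.03 (4 elements from -5.67 to -1.68) and CAV1, the main protein of caveolae, by -3.72 ± 0.20.

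Of 24 extracellular matrix and fibroblast genes, 19 were higher in adipose tissue (median -1.86), including MMP2 at -3.73 ± 0.14, COL3A1 at -3.61 ± 0.07, VIM at -3.51 ± 0.11 and DCN at -3.24 ± 0.12. FBLN2, named after its value was seen, was the exception, higher in liver at 1.80 ± 0.04. Smooth muscle and pericyte markers had 6 of 11 genes higher in adipose tissue (median -1.05), led by MCAM at -3.09 ± 0.03. Fatty acid oxidation had 10 of 13 genes higher in liver (median 1.66), with ECI1 at 2.78 ± 0.03 and CPT1A at 2.64 ± 0.04. Cholesterol synthesis had 4 of 5 (median 2.23), led by MSMO1 at 4.03 ± 0.02, and xenobiotic metabolism 6 of 7 (median 3.16), with FMO5 at 4.30 ± 0.08. Hepatocyte plasma proteins had 4 of 5 genes higher in liver (median 2.48), and APOA1 at 0.08 ± 0.25 did not pass. Lipogenesis had 4 of 8 genes higher in adipose tissue and 1 higher in liver (median -1.01): ACLY, which makes cytosolic acetyl-CoA, stood at -1.93 ± 0.17, ME1 at -1.69 ± 0.19 and AGPAT2 at 1.46 ± 0.44. Epithelial markers had 4 of 17 genes higher in liver (median 0.37), with SPINT1 at 3.19 ± 0.23 and the keratin KRT18 at 1.76 ± 0.12. The mesothelial list, which shares KRT8, KRT18 and KRT19 of its 5 measured genes with the epithelial list, had a median of 0.63. The mesothelial list lay among random lists with the mean, after quantile normalisation (0.48) and without the Cy5 arrays (0.39).

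AHCY (3.57 ± 0.06), ASS1 (2.12 ± 0.09), GOT2 (2.27 ± 0.07) and GOT1 (1.58 ± 0.04) were higher in liver, with list medians of 1.10 for the urea cycle and 0.27 for gluconeogenesis. The latter lay among random lists with unmatched lists, with the mean, after quantile normalisation and without the Cy5 arrays (0.08), and the urea cycle did so without the Cy3 arrays (0.87). The secretory pathway had 5 of 40 genes higher in liver, led by PDIA4 at 1.84 ± 0.00, with a median of 0.20 that became -0.05 without centring. The proteasome list had 0 of 26 genes past the rule, and a median of 0.11, which turned to -0.15 without centring and to -0.01 without the Cy5 arrays. It lay among random lists with unmatched lists and with the mean. Ribosomal proteins had 4 of 43 genes higher in adipose tissue (median -0.55), including RPL35 at -1.32 ± 0.19. Of 20 myeloid markers 8 were higher in adipose tissue and 3 in liver (median -0.89), with CTSK at -2.65 ± 0.32 and S100A12 at -2.59 ± 0.33. That median was -0.00 when the subcutaneous depot was left out of the adipose mean. The other lists lay among random lists. They included the adipocyte markers, with 3 of 13 genes higher in adipose tissue and 2 in liver (median -0.36).

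In total 315 genes were higher in liver and 262 in adipose tissue out of 4326, against 22 in the dye contrast. A limma fit with the 3 depots as samples called 122 genes, but liver, with 1 sample, added no spread, and the 2 residual degrees of freedom came from unlike depots, so it is no test of the tissue difference. Without centring, the median difference of all genes was -0.32 (-0.06 with centring) and the split became 232 to 435.

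The third comparison set mammary gland against the mean of the 3 adipose depots. The medians of the milk secretion and epithelial lists lay above random lists in mammary gland, and those of the matrix, myeloid, ribosomal and respiratory chain lists lay below them. DNAJC12 differed by 5.31 ± 0.15 log2 units (39.6-fold), EHF, an epithelial transcription factor, by 4.33 ± 0.53 and ABCG2, which exports riboflavin and drugs into milk, by 4.31 ± 0.07. RETREG1, a receptor for turnover of the endoplasmic reticulum, stood at 4.17 ± 0.26 and PLIN2 at 3.38 ± 0.21. FN1 differed by -3.79 ± 0.06, COL1A2 by -3.61 ± 0.12 and COL3A1 by -3.54 ± 0.12.

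All 5 measured milk protein and secretion genes passed (median 2.78), with MFGE8 at 3.88 ± 0.42, MUC1 at 3.41 ± 0.87, XDH at 2.78 ± 0.03 and B4GALT1 at 2.40 ± 0.30. Epithelial markers had 10 of 17 genes higher in mammary gland (median 1.40), including KRT19 at 3.55 ± 0.45, ESRP1 at 2.48 ± 0.24 and CDH1 (E-cadherin) at 1.85 ± 0.34, and SPINT1, named after its value was seen, was lower at -1.19 ± 0.35. The mesothelial list followed through its keratins KRT19 and KRT8 (median 0.66). Nutrient transporters had 4 of 8 genes higher in mammary gland (median 0.89): SLC30A4 at 2.04 ± 0.26, SLC39A8 at 1.86 ± 0.08, SLC2A1 at 1.63 ± 0.11 and SLC29A1 at 1.18 ± 0.30. Lipogenesis had 3 genes higher in mammary gland and 2 lower of 8 (median 0.83), with AGPAT1 at 1.43 ± 0.33 and ACLY at -1.64 ± 0.14. Its median fell to 0.03, among random lists, without the arrays that carried the tissue in Cy3. The secretory pathway had a median of 0.30, above random lists, with SEC11C at 1.17 ± 0.12 as the 1 of 40 genes past the rule. SPP1 was higher in mammary gland at 2.98 ± 0.20, and APOA1 stood at -0.45 ± 0.27 without passing.

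Extracellular matrix genes had 18 of 24 genes higher in adipose tissue (median -1.50), with SPARC at -2.91 ± 0.12. Myeloid markers had 14 of 20 (median -1.90), with VSIG4 at -3.30 ± 0.27, CTSK at -2.98 ± 0.16 and CD68 at -2.60 ± 0.27. Their median was -0.87 with subcutaneous adipose tissue left out of the mean. Ribosomal proteins had 14 of 43 genes lower in mammary gland (median -0.61), with RPL37 at -1.72 ± 0.35 and RPS27 at -1.43 ± 0.26. The respiratory chain had 7 of 44 lower (median -0.55), with COX5B at -1.39 ± 0.03 and NDUFB8 at -1.24 ± 0.24. Fatty acid oxidation had 4 of 13 lower (median -0.62, and -0.51 among random lists without the Cy5 arrays), led by HADH at -1.80 ± 0.02. Adipocyte markers had 3 of 13 lower (median -0.57), with RBP4 at -3.23 ± 0.41, CEBPA, a transcription factor of fat cells, at -1.48 ± 0.45 and CAV1 at -1.24 ± 0.19. Their median was -1.08 with subcutaneous adipose tissue left out, and without the Cy3 arrays it stood at -0.57, close to the full value but among random lists. LDHA, a lactate dehydrogenase gene, stood at -2.22 ± 0.04, while its list lay among random lists, as did the other lists.

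In total 124 genes were higher in mammary gland and 290 in adipose tissue out of 4313, against 19 in the dye contrast. After quantile normalisation the split was 155 to 218. The limma fit with the depots as samples called 0 genes, under the same limit of 1 mammary gland sample without spread of its own.

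**Figure D2:**
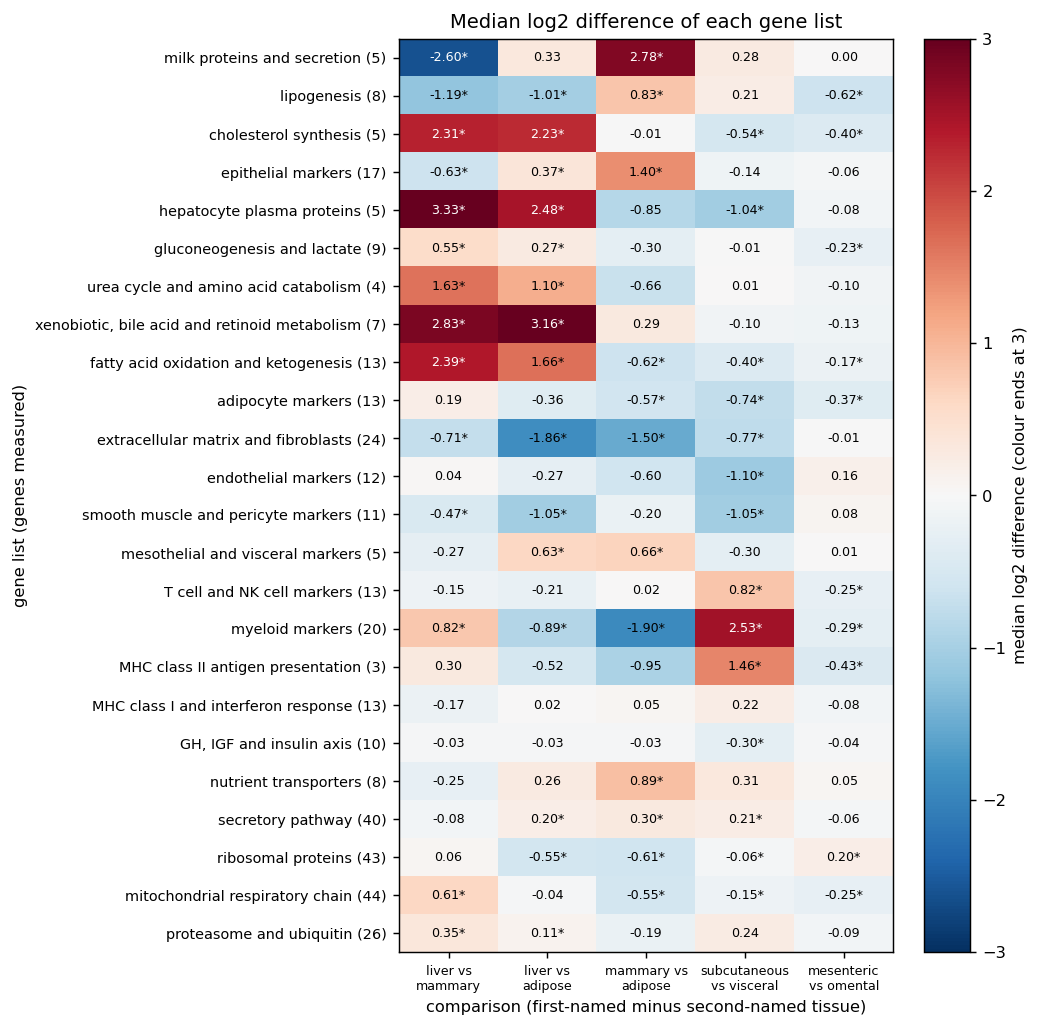
Median log2 difference of each gene list (rows, with the number of genes measured) in each comparison (columns), first-named minus second-named tissue. Colour and number give the median, and an asterisk marks lists outside the central 95% of 10000 matched random lists. Myeloid markers run from -1.90 in mammary gland against adipose tissue to 2.53 in subcutaneous against visceral adipose tissue.

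The fourth comparison set subcutaneous adipose tissue against the mean of the visceral depots, mesenteric and omental. Most myeloid markers were higher in the subcutaneous sample, and the medians of the adipocyte, endothelial, smooth muscle and matrix lists lay below random lists. S100A12, a granulocyte and monocyte protein, differed by 5.33 ± 0.09 log2 units (40.3-fold), the lysosomal lipase gene LIPA by 4.82 ± 0.12 (28.3-fold) and CYBB, the catalytic part of the phagocyte oxidase, by 4.33 ± 0.04. LGALS3 (galectin 3) differed by 4.09 ± 0.19, the chemokine receptor gene CCR1 by 3.84 ± 0.10 and LCP1, an actin bundler of leukocytes, by 3.53 ± 0.15. GPAT3, which starts triglyceride synthesis, differed by -3.44 ± 0.16, PTGDS by -2.79 ± 0.12, RBP4 by -2.60 ± 0.13 and PDK4, which restrains glucose oxidation, by -2.40 ± 0.05.

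Of 20 myeloid markers 15 were higher in subcutaneous adipose tissue, 1 was lower and 4 did not pass (median 2.53), with SPP1 at 3.92 ± 0.14 and LAPTM5 at 3.75 ± 0.06. The 3 genes of complement component C1q, named after their values were seen, lay on the other side: C1QC at -1.38 ± 0.34, which passed, and C1QB at -0.85 ± 0.15 and C1QA at -0.68 ± 0.11, which did not. The list of T cell and NK cell markers had 5 of 13 genes higher (median 0.82), with CD3E at 1.95 ± 0.29 and CD3D at 1.63 ± 0.30. Its members RAC2 (2.17 ± 0.06) and CORO1A (1.90 ± 0.14) are not confined to T and NK cells. CD8A, named after its value was seen, stood at -0.02 ± 0.07. MHC class II genes had 2 of 3 higher (median 1.46), BOLA-DRB3 at 1.51 ± 0.08 and CD74 at 1.46 ± 0.09. The glycolytic genes LDHA (3.39 ± 0.15) and ENO1 (1.41 ± 0.02) were also higher, while the median of their list lay among random lists. The immunoglobulin gene IGHM was higher at 1.45 ± 0.47.

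With myeloid markers up by a median of 2.53, endothelial markers had 7 of 12 genes lower (median -1.10), with EPAS1 at -1.57 ± 0.08 and CDH5 at -1.52 ± 0.22. Smooth muscle and pericyte markers had 6 of 11 lower (median -1.05), with MCAM at -2.43 ± 0.25 and TAGLN at -1.77 ± 0.04. Adipocyte markers had 6 of 13 lower (median -0.74), including CAV1 at -2.13 ± 0.06, LIPE, hormone-sensitive lipase, at -1.95 ± 0.15 and CAVIN1 at -1.82 ± 0.04. Extracellular matrix genes had 9 of 24 lower and 1 higher (median -0.77): COL4A1, a basement membrane collagen, at -2.07 ± 0.23, LAMC1 at -1.73 ± 0.07 and LAMA4 at -1.72 ± 0.01 were lower, and VIM, named after its value was seen, was higher at 1.10 ± 0.06. Among lipogenic genes ACLY stood at -2.13 ± 0.04, ACSL1 at -1.58 ± 0.01, ME1 at -1.32 ± 0.00 and SREBF1 at 3.52 ± 1.91, with a list median among random lists. Hepatocyte plasma proteins had 3 of 5 lower, with TF at -1.20 ± 0.03, C4A at -1.04 ± 0.04 and RBP4, and APOA1 higher at 1.64 ± 0.14 (median -1.04).

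Fatty acid oxidation had 4 of 13 genes lower (median -0.40), including ETFDH at -1.27 ± 0.09. Cholesterol synthesis (0 of 5 past the rule, median -0.54), the GH, IGF and insulin axis (PIK3R1 at -1.02 ± 0.05 past the rule, median -0.30), the respiratory chain (0 of 44, median -0.15) and ribosomal proteins (0 of 43, median -0.06) lay below random lists. Without centring, where the median difference of all genes was 0.64, these 5 medians were 0.23, 0.09, 0.33, 0.48 and 0.57, below that of all genes. Each of the 5 lay among random lists in at least 1 other setting. These were the mean and either orientation alone for the GH, IGF and insulin axis (-0.19 and -0.26), and the Cy3 arrays alone for cholesterol synthesis (-0.38), fatty acid oxidation (-0.35) and ribosomal proteins (-0.00). Ribosomal proteins also lost their place with unmatched lists and stood at 0.07 against omental adipose tissue alone. Against mesenteric adipose tissue alone, chosen after seeing the data, cholesterol synthesis (-0.30), fatty acid oxidation (-0.27) and the respiratory chain (-0.03) did so too. The secretory pathway lay above random lists (0 of 40 past the rule, median 0.21), but not with the mean or against omental adipose tissue alone (0.16). The other lists lay among random lists.

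In total 270 genes were higher in subcutaneous and 161 in visceral adipose tissue out of 4332, against 13 in the dye contrast. Without centring the split was 858 to 40. Of 91 genes past the rule with several elements, 89 had all elements in the same direction, and 60 had all of them past 2-fold. Agreement of clones was what the print layout had been chosen for, so it is no independent support here either.

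**Figure D3:**
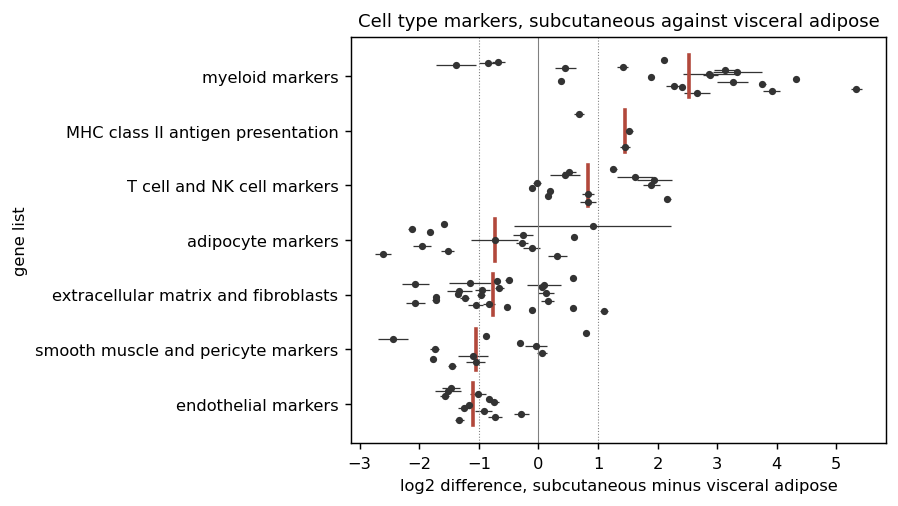
Log2 difference of subcutaneous minus visceral adipose tissue (horizontal axis) for each measured gene of 7 marker lists (rows). Points are genes, bars their dye orientation error, red lines list medians and dotted lines the 2-fold limits. Myeloid markers had a median of 2.53 and endothelial markers one of -1.10.

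The fifth comparison set mesenteric against omental adipose tissue. The depots differed little, with 36 genes higher in mesenteric and 25 in omental adipose tissue out of 4340. The same rule gave 28 genes of either sign in the dye contrast, which by construction holds none of these 61. CDK5R1 differed by 2.77 ± 0.50 log2 units, EPSTI1 by 2.16 ± 0.04, the tight junction gene CLDN1 by 1.76 ± 0.16 and KRT19 by 1.72 ± 0.32. CA2 (carbonic anhydrase 2) differed by -2.60 ± 0.39, UBE2Q2 by -2.02 ± 0.17 and SMDT1, part of the mitochondrial calcium uniporter, by -1.96 ± 0.17. Errors were wide for other leading genes, such as NR4A1 at 3.10 ± 1.86, CXCL14 at -2.62 ± 2.08 and CASD1 at -2.53 ± 1.83.

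Gene lists moved by less than 2-fold. The lipogenesis median (-0.62) lay below random lists with 1 of 8 genes past the rule, ACLY at -1.06 ± 0.11, while AGPAT2 (-2.56 ± 2.82), ACSL1 (-0.83 ± 0.11) and PLIN2 (-0.73 ± 0.08) did not pass. Adipocyte markers had a median of -0.37, also below random lists, although LIPE was higher in mesenteric adipose tissue at 1.14 ± 0.40. Cholesterol synthesis (median -0.40), the respiratory chain (-0.25), gluconeogenesis (-0.23), fatty acid oxidation (-0.17), T cell and NK cell markers (-0.25), myeloid markers (-0.29) and MHC class II genes (-0.43) also lay below random lists, with SPP1 at -1.07 ± 0.08 the only gene of these past the rule. Without the Cy5 arrays the medians of adipocyte markers (-0.09), gluconeogenesis (-0.19), fatty acid oxidation (-0.17), T cell and NK cell markers (-0.17) and MHC class II genes (-0.36) lay among random lists, and gluconeogenesis did so with the mean. Ribosomal proteins lay above random lists (0 of 43 past the rule, median 0.20, and -0.12 without centring). The matrix genes FBLN1 (1.41 ± 0.15) and FN1 (1.18 ± 0.01) were higher in mesenteric adipose tissue, with a list median of -0.01, and APOA1 stood at -0.23 ± 0.26 without passing. The other lists lay among random lists.

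With elements whose neighbouring spots disagreed left out, an alternative chosen after seeing the data, 17 of the genes past the rule were counted. With each orientation required to pass alone there were 29. Without centring the median difference of all genes was -0.33 and the split was 19 to 74.

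Genes highest in one tissue numbered 176 in liver, 151 in subcutaneous adipose tissue, 50 in mammary gland, 6 in mesenteric and 2 in omental adipose tissue, and 31 genes led in adipose tissue as a whole. This ranking rests on the likely direction of the ratios: with the direction turned, other genes would lead, 46 in liver, 7 in subcutaneous adipose tissue, 46 in mammary gland, 2 in mesenteric and 1 in omental adipose tissue, and 20 in adipose tissue as a whole. SERPINA3-3, a serpin gene, had the largest liver margin over the next tissue at 7.47 log2 units, ahead of UNC13D (7.08), HAVCR1 (7.01), LOC616364 (6.61) and TMT1B (5.80), each measured on 1 element with a dye orientation error of 0.80 to 3.48 in single tissues. Part of that error stayed in differences between tissues, as for SERPINA3-3 in liver against adipose tissue (8.21 ± 0.92) and TMT1B in liver against mammary gland (7.11 ± 1.19). EHF (3.88), RETREG1 (3.84), MFGE8 (3.51), DNAJC12 (3.18) and MUC1 (3.09) led in mammary gland. S100A12 (5.26), LIPA (4.22), CYBB (4.12), LGALS3 (3.92) and LOC514170, listed under the older name CSTB (3.85), led in subcutaneous adipose tissue. PRSS22 (1.57), FBLN1 (1.41), PLN (1.25), MFAP4 (1.18) and LIPE (1.14) led in mesenteric adipose tissue, and FLT1 (1.48) and ACLY (1.06) in omental adipose tissue, where the dye orientation error of FLT1 was 1.49, as large as its margin. COL1A2 (3.14), COL3A1 (2.77), HTR6 (2.43), CST3, cystatin C (2.36), and SPARC (2.20) led in adipose tissue as a whole. The name HTR6, a serotonin receptor gene, rests on 1 element, and a wrong name cannot be told apart from true expression. Its values over the 5 tissues lay close to those of SPARC, such as 2.56 and 2.16 in omental adipose tissue and -1.39 and -1.41 in liver.

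**Figure D4:**
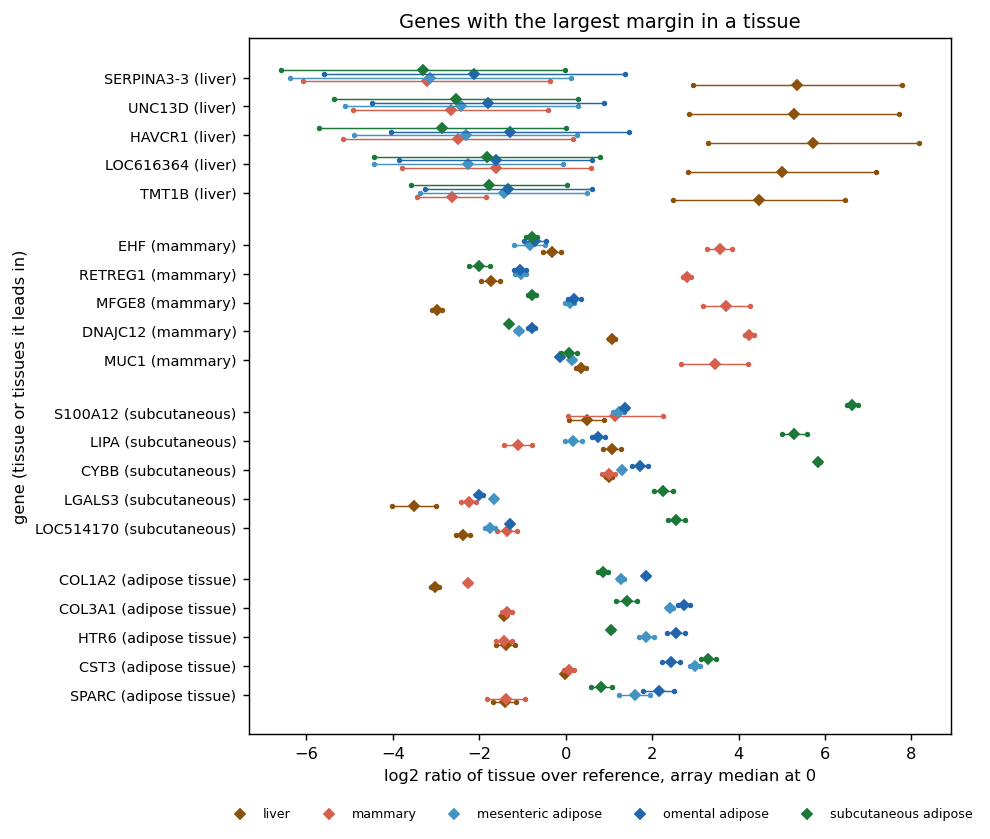
Log2 ratio of tissue over reference (horizontal axis) of the 5 genes with the largest margins in liver, mammary gland, subcutaneous adipose tissue and adipose tissue as a whole (vertical axis). Diamonds are tissue means and small points the 2 arrays of opposite dye orientation. S100A12 stood at 6.63 in subcutaneous adipose tissue and at 1.37 or below in the other tissues.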

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

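The tests of marker lists against each other, the agreement of elements and the leaving out of disagreeing spots were chosen after the results were seen. Quantile normalisation had been planned, but the bound it was held to was set afterwards. Elements without a usable gene name were not part of the comparisons, and many of them differed between tissues. By the same size rule 336 unnamed elements differed between liver and mammary gland (77 in the dye contrast), 319 between liver and adipose tissue (46) and 213 between mammary gland and adipose tissue (40). Between subcutaneous and visceral adipose tissue 272 differed (39), and between mesenteric and omental adipose tissue 105 (69). The largest difference of an unnamed element was -7.85 log2 units in liver against mammary gland.

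The median of myeloid markers was 2.53 log2 units higher in subcutaneous than in visceral adipose tissue. Scaling between arrays argues poorly for it, because the median was 2.22 (bootstrap interval over genes 1.48 to 2.86) after quantile normalisation. A lower share of adipocytes alone would raise other cell types alike, but the endothelial median minus the myeloid one was -3.63 (interval -4.34 to -2.62). For lymph node tissue as the whole cause, T cell markers were taken to rise at least as far. Their median differed from the myeloid one by -1.71 (interval -2.68 to -0.45), though it was itself higher in subcutaneous adipose tissue, at 0.82. How far a list rises also depends on its level in visceral adipose tissue, and channel intensities were not analysed. The comparison therefore does not decide on lymph node tissue. All 3 intervals are over genes of the same RNA samples, which may vary together. A larger number of myeloid cells in this sample, whether of this depot, of this animal or of the place sampled, may be the source and stays open with 1 RNA sample, as does a swap with a sample outside the series.

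Between mesenteric and omental adipose tissue 61 genes passed the size rule. Leaving out elements whose neighbouring spots differed by more than 1 log2 unit on any array took the count to 17, and 38 of the 44 genes lost had no element left. In the other 4 comparisons 89.3% to 92.7% of the count stayed. The dye contrast count fell from 28 to 1 with the same elements left out, so noise of single spots may account for much of the list. A difference between the depots remains untested for the 17 genes.

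Genes with the largest liver margin included UNC13D and HAVCR1, which are not known chiefly as liver genes. A wrong gene name cannot be told apart from true expression, because each has 1 element. Of 115 genes with several elements past the rule in liver against adipose tissue, 5 had elements that differed in direction, but the print layout was chosen for agreement of clones and the genes by their mean, so this gives no share of wrong names.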

How the results depend on the processing

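Leaving out elements with disagreeing spots, keeping ceiling values, setting subcutaneous against 1 visceral depot, leaving subcutaneous adipose out for gene lists and turning the direction of the ratio were chosen after the results were seen. Counts at 1.5-fold, at 3-fold and with elements counted singly were 1233, 281 and 1130 for liver against mammary gland, 1230, 254 and 1081 for liver against adipose tissue and 1062, 141 and 771 for mammary gland against adipose tissue. They were 915, 173 and 838 for subcutaneous against visceral and 192, 19 and 198 for mesenteric against omental adipose tissue. These shifts follow from the thresholds and from counting more units. Without centring, the last 2 comparisons gave 898 and 93 genes. Mesenteric against omental adipose tissue gave 29 genes with each orientation past 2-fold, 17 without disagreeing spots, 102 to 108 from single orientations, and 137 with the omental Cy5 array left out, where the dye offset no longer cancels. Genes highest in one tissue numbered 781 at a 1.5-fold and 192 at a 3-fold margin, and 102 with the direction turned, where genes lowest in a tissue become highest. With depots as samples, limma called 122 genes for liver and 0 for mammary gland against adipose tissue, with all spread taken from 3 unlike depots and none from the 1 liver or mammary gland sample. Without centring, list medians changed sign for the secretory pathway (-0.054) and the proteasome (-0.145) in liver against adipose tissue. In subcutaneous against visceral adipose tissue they did so for cholesterol synthesis (0.091), fatty acid oxidation (0.227), the GH, IGF and insulin axis (0.328), ribosomal proteins (0.570) and the respiratory chain (0.475), and in mesenteric against omental adipose tissue for ribosomal proteins (-0.118). All genes shift together in that setting. The proteasome median in liver against adipose tissue ran from -0.013 to 0.236 over single orientations, and the ribosomal median was 0.071 for subcutaneous against omental adipose tissue alone. CEBPD in mesenteric against omental adipose tissue had an element at -3.28 and one at 0.255, so it changed sign to 0.255 both with the element of smallest dye difference and without disagreeing spots. Of 65 list results outside random lists, 63 stayed so after quantile normalisation, 59 without the Cy3 arrays and 50 without the Cy5 arrays, and the cause was not tested.

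Of 40 alternative values of distances between tissues 28 moved by more than the spread of the orientations. After quantile normalisation the distance of liver was 0.802 to mammary gland, 0.795 to mesenteric, 0.771 to omental and 0.910 to subcutaneous adipose tissue, that of mesenteric to omental adipose tissue 0.336 and that of omental to subcutaneous adipose tissue 0.683. With equal median absolute deviation the same distances were 0.747, 0.807, 0.756, 0.968, 0.349 and 0.749, and mesenteric to subcutaneous adipose tissue 0.805. Over single orientations, where noise of the dye is not averaged, liver ran from 0.912 to 0.989 from mammary gland, 0.898 to 0.911 from mesenteric, 0.856 to 0.868 from omental and 1.028 to 1.033 from subcutaneous adipose tissue. Mammary gland ran from 0.686 to 0.809, 0.680 to 0.765 and 0.826 to 0.920 from the same depots. Mesenteric ran from 0.386 to 0.402 from omental and 0.721 to 0.777 from subcutaneous adipose tissue, and omental from 0.679 to 0.699 from subcutaneous adipose tissue. The cause was not tested.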

Other observations

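The C1q genes followed the other myeloid markers in some comparisons only. C1QA, C1QB and C1QC were higher in liver than in mammary gland (2.90, 3.07 and 2.48) and lower in mammary gland than in adipose tissue (-2.20, -1.92 and -1.40), where the list medians were 0.82 and -1.90. In liver against adipose tissue, where the list median was -0.89, C1QB (1.15) and C1QC (1.08) were higher in liver and C1QA (0.70) did not pass. In subcutaneous against visceral adipose tissue they were the only myeloid markers below 0 (-0.68, -0.85 and -1.38), while CD163, a scavenger receptor, stood at 0.45 ± 0.18 and FCGR3A at 0.38 ± 0.04. CD68 (3.34 ± 0.41), ITGB2 (3.26 ± 0.26), CD48 (3.12 ± 0.18) and MSR1 (2.40 ± 0.05) were higher in the subcutaneous sample. These genes were picked after their values were seen, and no cause was tested.

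SPP1 counted as a myeloid marker but was higher in mammary gland than in liver and than the mean of the 3 adipose depots. It stood 3.92 ± 0.14 higher in subcutaneous than in visceral adipose tissue. The difference from the adipose mean therefore need not hold against subcutaneous adipose tissue alone. The 2 elements of SPP1 had the same direction and unlike sizes, -7.96 and -3.72 in liver against mammary gland and 2.02 and 3.94 in mammary gland against adipose tissue. In subcutaneous against visceral adipose tissue they stood at 2.94 and 4.89.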
